A study of Mus musculus with 4 samples.

How the data were processed

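Open chromatin was profiled with the Omni-ATAC protocol, with 50000 cells per Tn5 reaction per the labels' protocols, in B16F10 melanoma cells with a scrambled guide (sgScramble, n = 2) or a guide against Arid1a (sgArid1a, n = 2). Groups and replicate numbers were taken from the sample titles. Peak names inside the sgScramble lists begin with sgNT, and the group name follows the titles. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical.

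The authors deposited a broad peak list per library, so peaks were called per library and not on pooled reads. Each peak carries a score, a fold (a ratio of signal over background), a −log10 p-value and a −log10 q-value, all as deposited by the authors. The deposited score was the whole-number part of 10 times the −log10 q in 99.99% to 100% of peaks. The lowest −log10 q was just above 1 in every list. The submitters' processing notes name STAR 2.5.3a and HOMER and the builds GRCm38 and mm10, without giving their roles. The peak caller, and whether read ends were shifted for the Tn5 offset, are not given in the sources used here. The fold and the −log10 values depend on depth and background, so regions were ranked or filtered by them within a list only. Between lists, their medians were compared to describe the lists and to weigh depth. Depth is unknown, since the lists hold no counts. Confidence intervals therefore cover counting error over regions only.

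Peaks on chromosomes 1 to 19, X and Y were merged into union regions where they overlapped by at least 1 bp, and a list had a region when any of its peaks overlapped it by at least 1 bp. Lost regions had a peak in both sgScramble lists and in neither sgArid1a list, gained regions the reverse. Shares of lost regions were taken over regions in both sgScramble lists, and shares of gained regions over regions in both sgArid1a lists. Strength was the mean percentile of the authors' fold within the sgScramble lists for lost shares and within the sgArid1a lists for gained shares. Where a list had several peaks in a region, the highest percentile was taken. Genes came from a RefSeq table of GRCm38.p6 (21887 protein-coding genes), the build of the mm10 coordinates. That table gives no strand, so either end of a gene was used where a transcription start site had been planned: gene-end regions lay within 1 kb of a protein-coding gene's boundary, and other regions are called distal. A region was assigned to the protein-coding gene with the nearest end within 50 kb, and covered length was taken within 2 kb of both ends. A genome sequence was not used here, so the planned comparison of motif shares was not run.

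Libraries were compared by an exact permutation test of group means. The counts of lost and gained regions were set against the splits that pair libraries across the groups. Gene-end shares were compared by Fisher's exact test, two-sided. For each of 18 gene lists (413 symbols, 3 of them not matched to a protein-coding gene and 7 matched through a synonym), the lost and gained shares were set against 10000 random lists matched on regions per gene, two-sided, with Benjamini-Hochberg adjustment over 36 tests. The smallest p those random lists can give is 0.0002. The named genes were Arid1a, up to 3 genes per list with the most lost and up to 3 with the most gained regions, the 10 genes with the most of each over all genes, the 5 strongest lost and gained regions, and Ifnb1, Isg15, Cxcl10, Mitf, Tyr and Cd274. Groups, tests, gene lists, this rule and the settings listed next were set before the data were examined.

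The alternatives were a stricter q, the upper 50% of each list by fold, lists of equal length, wider merging, a 50% overlap without merging, a width minimum of 500 bp, all sequences, presence and absence held to different thresholds, a window of 2.5 kb, strata of width, assignment within 10 kb, expectation by strength, leaving out each library in turn, and the replicate number as a block. Equal-length lists with presence by their upper 50%, pairs of equal-length lists, strata of width in a group's own lists, and strata of fold percentile or −log10 p with width were added after the results were seen. On lists simulated from 103629 regions, planted lost and gained regions were counted if the simulation had placed them in both lists of their group. Of these, 164 of 164 lost and 167 of 167 gained regions were recovered. This checks the merging and overlap steps and not the power to detect a loss. In the list test over 16356 genes, 20 of 20 lists of 30 genes with 35% of regions lost had an unadjusted p under 0.05, as did 6 of 200 unchanged lists. The planted share lies above the lost share of every gene list in the main setting. No smaller share was planted, so the power for smaller shifts, or after adjustment, was not checked. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.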

Results

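Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in B16F10 cells, a mouse melanoma line grown in vitro. The 4 libraries fell into 2 groups of 2: cells carrying a scrambled guide RNA (sgScramble) and cells carrying a guide against Arid1a (sgArid1a). Arid1a encodes a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. The series title places the gene upstream of R-loops, which are RNA:DNA hybrids, of the DNA-sensing adaptor STING and of type I interferon. The question addressed here was which accessible regions differed between the groups. Each library was represented by the authors' own list of broad peaks, called per library. The lists held 82319 and 85613 peaks in sgScramble replicates 1 and 2, and 65353 and 71255 in sgArid1a replicates 1 and 2. The lists hold no read counts, so the sequencing depth of each library is unknown.

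At Arid1a itself (GRCm38, chromosome 4, 133679008 to 133756769), 3 accessible regions of the sgScramble cells were missing from both sgArid1a lists and 4 were present in all 4 lists. The 3 missing regions all lay in the gene body, at 133688633 to 133690726, 133738115 to 133738815 and 133745646 to 133746097. They were among the weaker peaks of the sgScramble lists, with mean fold percentiles of 6.31, 9.37 and 18.6. The region over the gene end at 133756314 to 133757761 was present in all 4 lists. Peaks within 2 kb of the ends of Arid1a covered 1368 ± 119 bp in sgScramble and 1385.5 ± 4.95 bp in sgArid1a cells (SD, n = 2 each). A guide-directed edit need not remove a peak, so the lists do not check that Arid1a was disrupted.

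**Figure D1:**
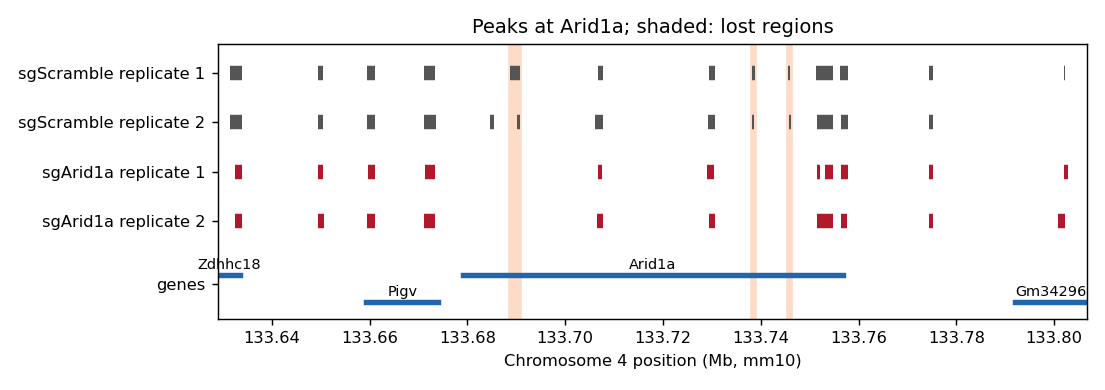
Peaks around Arid1a on chromosome 4 (position in Mb, horizontal axis), with 1 row of boxes per library and the protein-coding genes beneath; shading marks the 3 regions with a peak in both sgScramble lists and in neither sgArid1a list. The 4 regions assigned to Arid1a and shared by all lists include the 1 over the gene end at 133756314 to 133757761. Other regions in the plot that are shared by all lists were not assigned to Arid1a.

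The sgArid1a lists were shorter and covered less of the genome than the sgScramble lists. The mean number of peaks was 68304 ± 4173 in sgArid1a and 83966 ± 2329 in sgScramble libraries (SD, n = 2 each), a difference of -15662 peaks or -18.7%. Peaks covered 58.2 ± 6.26 Mb in sgArid1a and 74.8 ± 1.3 Mb in sgScramble libraries, a difference of -22.3%. The median −log10 p of the peaks was 7.06 and 7.62 in the sgArid1a lists and 9.20 and 9.02 in the sgScramble lists. The median peak width was 703.5 ± 40.3 bp against 748.5 ± 7.78 bp. Both sgArid1a libraries lay below both sgScramble libraries in peak number, covered length and median width, and the exact two-sided permutation p was 0.333 for each, the smallest that 2 libraries against 2 can give. By covered length, the sgScramble lists overlapped each other with a Jaccard index of 0.700 and the sgArid1a lists with 0.621. The 4 pairs across the groups ranged from 0.568 to 0.623, so the sgArid1a replicates were no more alike than sgArid1a replicate 2 was to sgScramble replicate 1.

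Regions with a peak in both sgScramble lists were missing from both sgArid1a lists far more often than the reverse. The margin was smaller with lists of equal length, at 4105 against 2361 regions. Merging the 4 lists gave 103629 regions, of which 52885 (51.0%) held a peak in every list. A peak in both sgScramble lists and in neither sgArid1a list, called lost, was found at 9388 regions, or 12.9% of the 73056 regions present in both sgScramble lists (95% Clopper-Pearson interval 12.6% to 13.1%). For the genes with the most lost regions, numbers are given out of their regions present in both sgScramble lists. Among them were Gsk3b, a kinase of Wnt and insulin signalling, with 6 of 14 lost, and Gnao1, a G protein alpha subunit, with 6 of 12. Chn2, Acsf3 and Rapgef2, an exchange factor for Rap GTPases, also had 6 each, of 17, 11 and 12 regions. Tasp1, Tns1, Mylk3, Prune2 and Igsf3 had 5 each, and at Mylk3 these were 5 of the 6 regions present in both sgScramble lists. Gsk3b lies on chromosome 16 at 38089001 to 38246084 and Gnao1 on chromosome 8 at 93810153 to 93969388.

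The 9388 lost regions were 5.35 times as many as in the highest of the 4 splits that pair an sgScramble with an sgArid1a library. Those splits gave 793, 1300, 1061 and 1756 regions. With 3 ways to divide 4 libraries into pairs, no p-value under 0.333 can be reached. The count depended on the libraries and on list length. It was 17772 without sgScramble replicate 1, 15535 without sgScramble replicate 2 and 16888 without sgArid1a replicate 2, since fewer lists then have to agree. As called, both sgScramble lists were longer than both sgArid1a lists, which by itself can raise the count above splits that mix them. With lists of equal length the count was 4105, against 1123 in the highest split across the groups.

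Regions with a peak only in the sgArid1a lists were few in the lists as called. A peak in both sgArid1a lists and in neither sgScramble list, called gained, was found at 771 regions, or 1.39% of the 55449 regions present in both sgArid1a lists (95% interval 1.29% to 1.49%). As called, that number lay below each of the 4 splits across the groups. It also lay below the highest of them at a −log10 q of at least 5 (84 against 538), with merging within 1 kb (793 against 1784), with peaks of at least 500 bp (484 against 1492), with a 50% overlap (1007 against 2340) and with presence by the upper 50% of each list and absence against full lists (31 against 69). It lay above the highest with lists of equal length (2361 against 1123), with only the upper 50% of each list by fold (1230 against 872), and with equal-length lists and presence by their upper 50% (40 against 36), a setting chosen after the results were seen. At most 2 gained regions were assigned to any gene, and 12 genes had 2. Among them were Cux1, a homeobox transcription factor, Ogt, the enzyme that attaches O-GlcNAc to proteins, Dusp16, a phosphatase of MAP kinases, and Il16, a cytokine. The others named by the rule were Zfp280d, Cecr2, Zfp830, Phf14, Rasgef1a and Epop. The gained count was 1579 and 1757 without sgScramble replicate 1 or 2 and 5681 and 4869 without sgArid1a replicate 1 or 2.

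**Figure D2:**
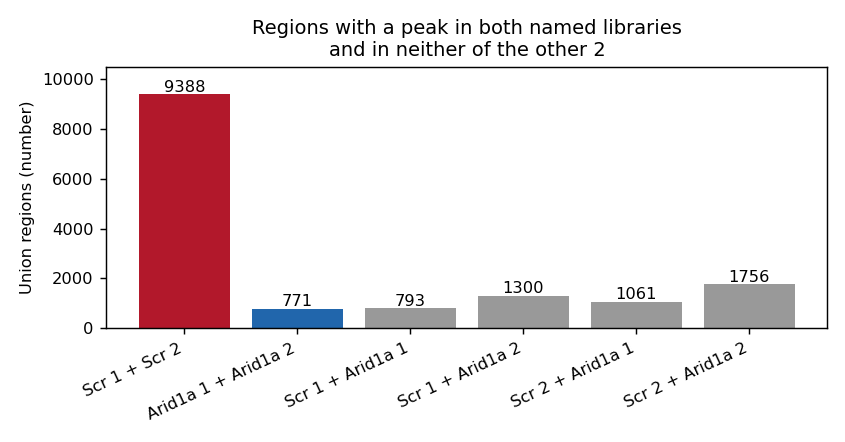
Number of regions (vertical axis) with a peak in both named libraries and in neither of the others, for the 6 pairs of libraries; Scr stands for sgScramble and numbers for replicates. The pair of sgScramble libraries shared 9388 such regions and the pair of sgArid1a libraries 771, against 793 to 1756 for the pairs across the groups.

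The strongest lost region lay on chromosome 10 at 23526010 to 23527321, between genes and 175172 bp from the nearest protein-coding gene end, that of Eya4, a transcriptional coactivator. Its mean fold percentile within the sgScramble lists was 99.1. The next were at 58466406 to 58466878 on chromosome 5 (nearest gene Pcdh7, a protocadherin, 98.5), at 14325991 to 14326277 on chromosome 2 inside Mrc1, the macrophage mannose receptor gene (98.1), at 112882937 to 112883658 on chromosome 10 (nearest gene Atxn7l3b, 97.3) and at 39518559 to 39519173 on chromosome 9 (nearest gene Olfr957, an olfactory receptor, 97.2). Such strong losses were rare: the median lost region stood at percentile 27.8, 1676 lost regions (17.9%) stood above the 50th percentile and 141 above the 80th. Gained regions were weaker within their own lists, with a median percentile of 20.5, and 46 of them (5.97%) stood above the 50th. The strongest gained region, at 114614233 to 114614617 on chromosome 6, lay 28510 bp from an end of Atg7, an autophagy gene, at percentile 76.0. The next gained regions lay nearest to Trim24 (chromosome 6, 37744811 to 37745102), F830045P16Rik (chromosome 2, 129438915 to 129439194), Helt (chromosome 8, 46281514 to 46281960) and Selenoi (chromosome 5, 30247638 to 30248029).

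**Figure D3:**
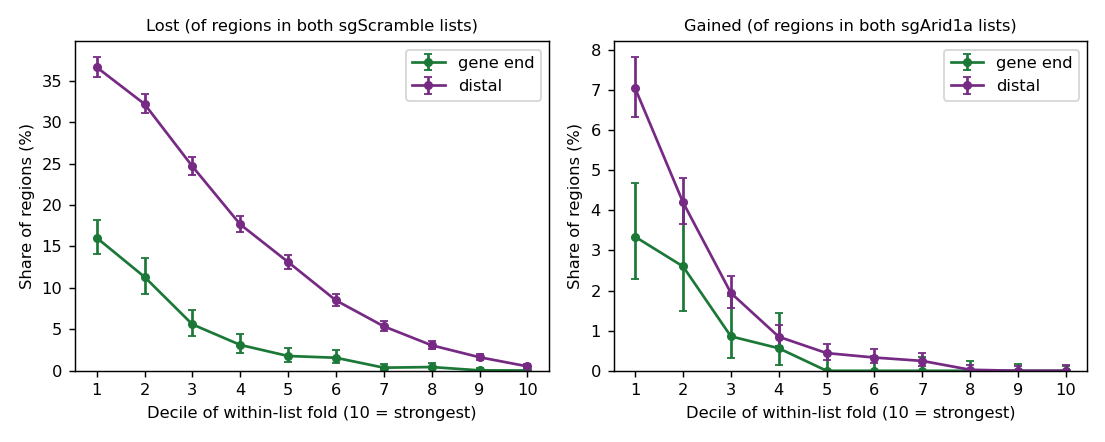
Share of regions lost (left) or gained (right), in percent, by decile of mean within-list fold, for regions within 1 kb of a protein-coding gene end and for distal regions; error bars are 95% Clopper-Pearson intervals. In the weakest decile 36.6% of distal and 16% of gene-end regions were lost, and in the strongest 0.536% and 0.0354%.

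Losses lay away from the ends of genes, which include the promoters. Of the 9388 lost regions, 423 (4.51%) were within 1 kb of an end of a protein-coding gene, against 12667 of the 52885 regions present in all lists (24.0%). The odds ratio was 0.150 (95% interval 0.136 to 0.165; Fisher's exact test across regions, two-sided, p at most 1e-300). Lost regions were most often inside gene bodies (53.7%) or between genes (33.5%), and regions in all lists less often (41.7% and 26.4%). Among the regions present in both sgScramble lists, the lost share rose with distance, from 3.08% (423 of 13751; 2.79% to 3.38%) within 1 kb of a gene end to 13.4% at 1 to 10 kb, 14.3% at 10 to 50 kb, 16.1% at 50 to 100 kb and 19.95% (1759 of 8817; 19.1% to 20.8%) beyond 100 kb. Distal regions inside protein-coding genes (15.3%) and outside them (14.8%) were lost at close to the same share.

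The gene-end losses included a region 169 bp from an end of Hbegf, an EGF receptor ligand, on chromosome 18 at 36504344 to 36504758, at percentile 91.4, which was chosen after its values were seen. Within the sgScramble lists alone, peaks covered a median of 469.5 bp of a lost region and 973 bp of a region in all lists. The odds ratio moved to 0.349 within strata of merged width, which includes sgArid1a peaks in regions of all lists. It moved to 0.417 within strata of the sgScramble width, chosen after the results were seen. A ratio of 0.429 came from strata of fold percentile and that width, also chosen afterwards. There, lost regions were compared with all other regions in both sgScramble lists, not only with those in all lists. The step to 0.429 is therefore not due to the strata alone. Gained regions were also rarer at gene ends, with 58 of 771 (7.52%) and an odds ratio of 0.258 (0.197 to 0.338; Fisher's exact test, p = 1.03e-32). For gained regions the call ended within strata of width (0.765, interval 0.580 to 1.01), and the direction turned with the upper 50% of each list by fold (1.17, interval 1.04 to 1.32). Regions are not replicates, so these tests describe the 4 libraries.

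**Figure D4:**
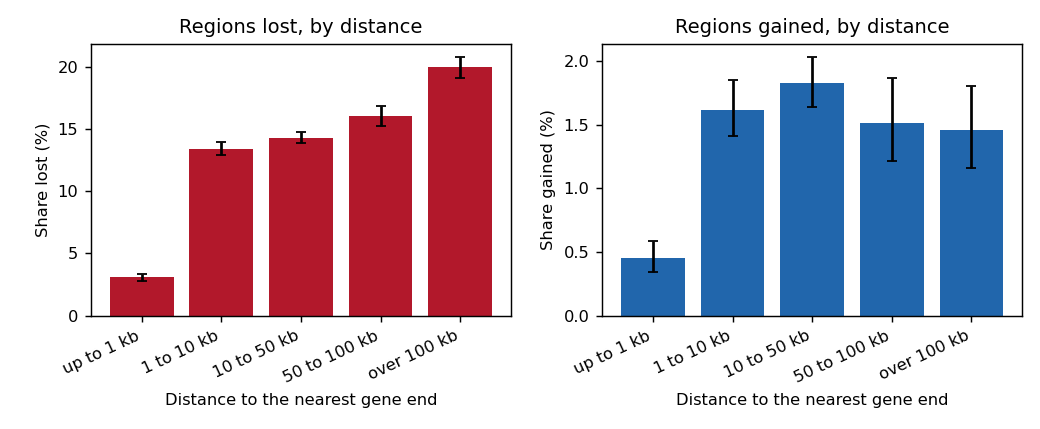
Share of regions lost (left, of those in both sgScramble lists) and gained (right, of those in both sgArid1a lists), in percent, by distance to the nearest end of a protein-coding gene; error bars are 95% Clopper-Pearson intervals. The lost share goes from 3.08% within 1 kb to 19.95% beyond 100 kb, and the gained share from 0.451% within 1 kb to between 1.46% and 1.83% farther away.

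Losses were found on every chromosome but Y. The lost share ranged from 10.6% on chromosome 11 (9.74% to 11.4%) to 15.5% on chromosome 16 (14.2% to 17.0%). Chromosome 4, which carries Arid1a, had 11.8%, and the X chromosome 13.9%. On the Y chromosome 0 of 8 regions were lost, which allows a share of up to 37.5% (3 counts of 8; the Clopper-Pearson upper limit is 36.9%). The gained share ranged from 0.932% on chromosome 10 to 2.19% on chromosome 6. Without 1 of the 4 libraries the highest lost share, on chromosome 16 each time, was 24.1% and 21.8% (without sgScramble replicate 1 or 2) and 19.8% and 26.6% (without sgArid1a replicate 1 or 2), and it was 8.88% with lists of equal length. The chromosome with the highest gained share changed: it was chromosome 1 without sgScramble replicate 1 (3.83%) and with lists of equal length (5.24%), the X chromosome without sgScramble replicate 2 (4.28%), and chromosome 6 without sgArid1a replicate 1 or 2 (10.9% and 12.2%).

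Genes of the type I interferon response lost regions at close to the share of other genes. Of the 39 list members with a region in both sgScramble lists, 11 had a lost region, and 12 of their 101 regions were lost (11.9%, against 10.6% in random lists matched on regions per gene; unadjusted permutation p = 0.769). Samd9l had 2 lost regions and Ifit2, an interferon-induced tetratricopeptide gene, had 1. Ifit3, its neighbour in the same family, had the 1 gained region of the list. Ifnb1, the interferon beta gene (chromosome 4, 88522025 to 88522794), had 1 lost region at 88503776 to 88504160, 17865 bp from its nearer end, and 1 region present in all lists. A 269 bp peak 474 bp from Ifnb1 was called in sgArid1a replicate 1 but not in replicate 2, so the length covered near its ends was 134.5 ± 190 bp in sgArid1a and 0 bp in both sgScramble libraries. At Isg15, a ubiquitin-like interferon-stimulated gene, peaks covered 814.5 ± 19.1 bp in sgArid1a and 866.5 ± 53 bp in sgScramble cells (n = 2 each).

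In the cGAS-STING list 7 of 48 regions were lost (14.6%, expected 10.8%) and 0 of 39 were gained. Without sgScramble replicate 2 the lost share lay just below expectation (16%, expected 16.4%). The losses were at 5 of 17 genes, among them Mre11a, a DNA end-processing nuclease, and Trim32, with 2 regions each, and Prkdc, the DNA-dependent protein kinase. The interferon gamma list lost 10 of 99 regions (10.1%, expected 11.3%), with 2 at the kinase gene Jak1 and 2 at the transcription factor gene Irf2, and gained 1 region, at Cd74. Cd274, which encodes PD-L1, lost 0 regions and kept 2, and its ends were covered over 1062 ± 188 bp in sgArid1a and 955.5 ± 14.8 bp in sgScramble cells. Class I antigen presentation lost 4 of 35 regions (11.4%, expected 9.67%), with 1 each at H2-D1, Canx and Nlrc5. Chemokines and cytokines lost 8 of 77 (10.4%, expected 11.5%), including 2 of 12 at Tgfb2 and 1 each at Il15 and Il33. Cxcl10 lost 0 regions and kept 5, with 736.5 ± 105 bp covered at its ends in sgArid1a and 807.5 ± 261 bp in sgScramble cells. None of these lists differed from random lists by the permutation test (every adjusted p at least 0.655).

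Among genes for subunits of BAF, the complex that ARID1A belongs to, and of the related PBAF complex, 21 of 126 regions were lost (16.7%, expected 11.8%, unadjusted permutation p = 0.0992), at 12 of 28 genes. With lists of equal length the share lay below expectation instead, at 3 of 93 regions (3.23%, expected 5.95%). Arid1b, the paralog of Arid1a, and Arid1a itself had 3 lost regions each and Ss18 had 2. Peaks at the ends of Arid1b covered 2638 ± 83.4 bp in sgArid1a and 3311 ± 21.2 bp in sgScramble cells (n = 2 each), and the exact test cannot go below 0.333. Arid1b was named for its lost regions, and narrowing at gene ends was general. Gene-end regions in all lists covered 90.2% and 95.5% of the sgScramble mean in sgArid1a replicates 1 and 2. Arid2 and Actl6b had 1 gained region each, and Arid2 also had 2 lost regions. R-loop resolution genes lost 7 of 71 regions (9.86%, expected 10.49%), with 1 each at Top1, a topoisomerase, Aqr and Thoc2, and gained 0 of 59. DNA damage genes lost 9 of 81 (11.1%, expected 11.1%), with 2 each at Chek2 and Sesn2 and 1 at Atm, and gained 1 each at Wee1 and Msh6. Cell cycle genes lost 4 of 69 (5.80%, expected 11.2%), including 1 each at Aurka, Mcm5 and Mcm2, and gained 1 at E2f3. Housekeeping genes lost 4 of 66 (6.06%, expected 11.5%), including B4galt1, Ywhaz and Polr2a, and gained 0 of 55.

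Melanocyte lineage genes lost 22 of 204 regions (10.8%, expected 12.3%), at 13 of 29 genes. Mitf, the master transcription factor of melanocytes, Pax3, which acts upstream of it, and Zeb2 had 3 lost regions each. The same list had the highest gained count, 7 of 183 regions (3.83%, expected 1.49%), at 6 genes. The receptor gene Met had 2 of them beside 3 lost regions, and Mitf, Gpr143 and Zeb2 had 1 each. The gained share had an unadjusted permutation p of 0.0182 and an adjusted p of 0.655. With regions assigned within 10 kb it was 1 of 85 (1.18%, expected 1.13%), and without sgArid1a replicate 1 it lay below expectation (7.44%, expected 8.16%). Without sgScramble replicate 1 or 2 it was 6.52% (expected 3.24%) and 6.56% (expected 3.29%), and without sgArid1a replicate 2 it was 9.62% (expected 7.66%). With lists of equal length it was 15 of 172 (8.72%, expected 5.14%, unadjusted permutation p = 0.0396), which did not pass after adjustment. Mitf kept 14 regions, and Tyr, which encodes tyrosinase, lost 1 and kept 6. Peaks at the ends of Mitf covered 2480.5 ± 221 bp in sgArid1a and 2232 ± 755 bp in sgScramble cells, and those at Tyr 3161.5 ± 64.3 bp and 3318.5 ± 120 bp.

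TEAD-YAP genes lost 17 of 119 regions (14.3%, expected 12.7%), at 11 of 16 genes, and gained 0 of 93. The lost share lay below expectation without sgScramble replicate 2 (14.7%, expected 18.7%) and without sgArid1a replicate 1 (15.97%, expected 17.3%). Of the regions in both sgScramble lists, Yap1, the Hippo pathway coactivator (chromosome 9, 7931999 to 8004638), lost 5 of 11, Amotl1 lost 3 of 8 and Crim1 lost 1. AP-1 genes lost 12 of 117 (10.3%, expected 12.4%), including 3 at Cd44, which also gained 1, and 1 each at Hmga2 and Atf3. Mesenchymal and invasion genes lost 15 of 114 (13.2%, expected 12%), with 2 each at Itga5, Itgb3 and Zeb1, and gained 1 each at Lox and Egfr. Markers of other cell types gained 0 of 30 (endothelial), 0 of 29 (immune), 0 of 20 (fibroblast) and 0 of 3 (keratinocyte) regions. The expected shares were 1.21% to 1.46%, so few or no gains were to be found in lists of this size. Fibroblast markers lost 6 of 29 (20.7%, expected 11.1%), 2 of them at Pdgfra and 1 each at Lum and Postn. Immune markers lost 4 of 38 (10.53%, expected 10.8%), including Laptm5, Ptprc and Csf1r, and endothelial markers lost 4 of 43 (9.30%, expected 11.5%), including Kdr, Vwf and Eng. Keratinocyte markers lost 2 of 8 (25%, expected 9.55%), both at Trp63. Across the 18 lists and both directions, 0 of 36 tests passed an adjusted p of 0.05 by the two-sided permutation test with Benjamini-Hochberg adjustment, the lowest adjusted p was 0.655, and 1 test, the melanocyte gains, had an unadjusted p under 0.05. Over all settings run, 14 of the 18 lists lay on the other side of their expected share at least once for losses and 16 for gains; for losses the AP-1, housekeeping, fibroblast and keratinocyte lists did not. The adjustment ran over the lists alone, since no test was made per gene.

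**Figure D5:**
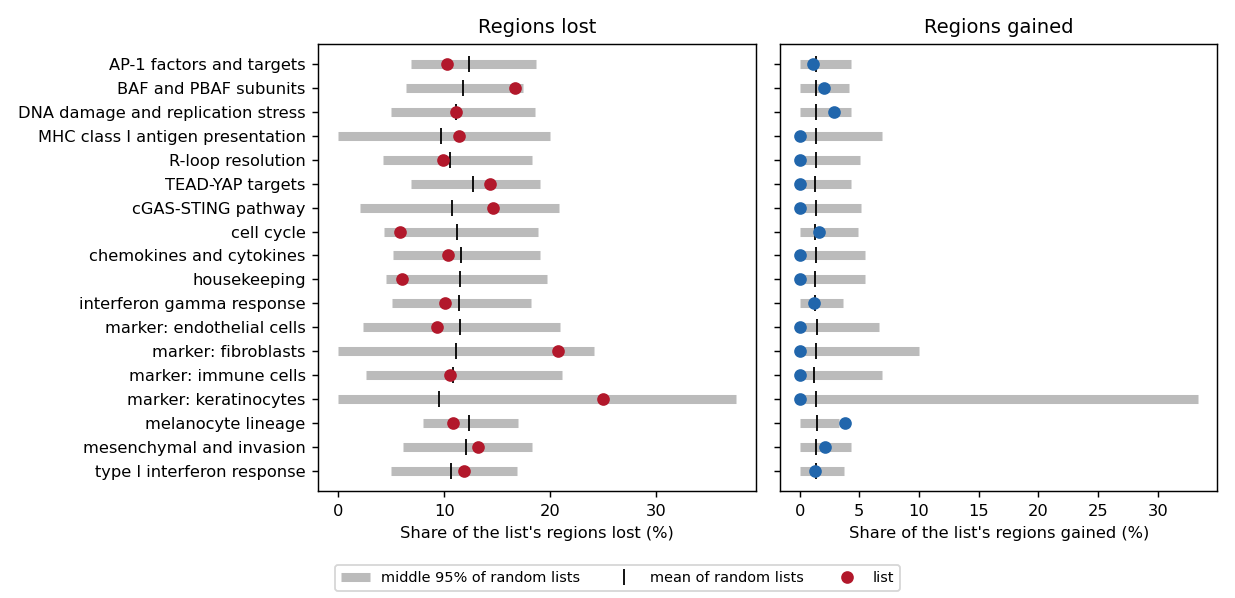
Share of each list's regions lost (left) and gained (right), in percent (circles), with the mean (tick) and the middle 95% (grey bar) of 10000 random lists matched on regions per gene. The melanocyte list's gained share of 3.83% lies outside its bar, with an adjusted p of 0.655.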

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

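The settings that combine equal list length with the upper 50%, and the strata of strength, were chosen after the results were seen. Lost regions outnumbered gained regions under every setting run. Counts of lost and of gained regions were 5500 and 1230 with the upper 50% of each list by fold, 4105 and 2361 with equal list length, 1114 and 31 with the upper 50% for presence and full lists for absence, and 553 and 40 with equal list length and the upper 50% for presence. Fewer peaks enter each of these settings, and the cause of the shifts was not tested further. Gained regions were 84 at a −log10 q of at least 5 (lost 10229) and 484 with peaks of at least 500 bp (lost 7088). Leaving out 1 library in turn gave 12716 to 17772 lost and 1579 to 5681 gained regions, as fewer lists must then agree. Merging within 1 kb (9226 and 793) and a 50% overlap (11993 and 1007) stayed within 1.5 times, and including all sequences changed nothing, since the lists hold no others. Settings with strata of strength or −log10 p compared lost or gained regions with all other regions in both lists of their group. The main setting compared them with regions in all lists, so shifts under those strata are not due to the strata alone. For lost regions at either gene end against distal ones, the odds ratio stayed below 1 and past its threshold in every setting (0.0836 to 0.541). For gained regions at either gene end against distal ones, it was 0.765 with strata of width, 0.829 with strata of strength and width, 0.996 and 0.861 with strata of the width in the sgArid1a lists alone or with strength, 1.17 with the upper 50% by fold, and 1.16 and 1.12 with 10 or 50 strata of −log10 p by width, none but the 1.17 with an interval clear of 1; the cause was not tested. No gene list passed in any setting (lowest adjusted p 0.396 to 1), and 4 to 5 of the 18 lists for losses and 4 to 7 for gains changed sides of their expected share with 1 library left out, as did 4 and 7 with equal list length and 5 and 5 with assignment within 10 kb. List tests with an unadjusted permutation p under 0.05 numbered 0 with assignment within 10 kb, 1 with equal list length and 3 with expectation by strength. These 3 were housekeeping losses, housekeeping gains and melanocyte losses. The difference in peaks per library was -18613 to -12711 with 1 library left out. For the lost and gained share per chromosome, the highest and lowest shares were 8.88% and 5.08% lost and 5.24% and 3.23% gained with equal list length. With 1 library left out they were 19.8% to 26.6% and 14.5% to 20.7% lost, and 3.83% to 12.2% and 1.90% to 6.34% gained. Of the values of single genes and lists under the alternatives, 1116 were labelled as staying within the bounds set for them and 390 as moved. All that moved were values of single genes. Every list value was labelled as staying, even where the list changed sides of its expected share, so the 1116 overstates stability. Among gene values, 86 moved and 88 stayed with the upper 50% by fold, and 20 moved and 154 stayed without sgScramble replicate 2. The other settings with gene values lay between these. Motif shares and their alternatives were not run, for want of a genome sequence. The files give no depth, so a missing peak shows only that no call was made.

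The replicate numbers did not pair the libraries: among the 4910 regions with a peak in 1 library of each group, 2549 fell in same-numbered libraries. Their excess over regions in differently numbered libraries was 0.0383 of the 4910. With the replicate block, the lost and gained counts are by construction 9388 and 771, the odds ratios were 0.193 for lost regions and 0.247 for gained regions, and 0 gene lists passed, while 7 of the 18 lists for losses and 6 for gains changed sides of their expected share.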

Other observations

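Tests of gene families, of pairs of equal-length lists, of runs and gatherings of losses, and of narrowing were chosen after the results were seen, as was the choice to name gene-end regions; the setting behind the list-length test and the strata were added after the counts of lost and gained regions were seen, with bounds set before their own values except for the strata of −log10 p and of width in a group's own lists. Among 196 families of genes that share a symbol stem (10 or more members), 0 of 392 permutation tests passed an adjusted p of 0.05, and 7 had an unadjusted p under 0.05. The lowest were Galnt, the enzymes that start O-linked glycosylation, with 18 of 80 regions lost (22.5%, expected 12%, unadjusted permutation p = 0.0094), and Krt, the keratins, with 11 of 49 (22.4%, expected 9.65%, permutation p = 0.0094). Wnt ligand genes stood on the other side with 3 of 82 regions lost (3.66%, expected 11.9%, permutation p = 0.0110). Each had an adjusted p of 1. The smallest p that the random lists can give is 0.0002, so 1 family alone could not pass over 392 tests. The count of 0 therefore does not decide whether some family lost regions together. Gene-end losses were spread over 422 genes, and the strongest after Hbegf were near Vta1, Slc14a2, Gm45975 and Zfp661. The 58 gene-end gains were at 58 genes, the strongest near Foxn2, a forkhead factor, at a fold percentile of 48.5. The lost share went from 8.29% at genes with 1 to 2 regions to 13.5% at genes with over 10, and from 13.6% to 14.5% when distal regions alone were counted.

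The excess of lost over gained regions was weighed against list length and depth. With lists of equal length and presence by the upper 50% of each by fold, the ratio of lost to gained regions was 13.8 (553 against 40), which argues against list length as the whole cause, although with equal length alone the counts were 4105 and 2361. Lower depth of the sgArid1a libraries stays open: the median fold of peaks at a −log10 p just above 10 was 4.71 and 4.47 in sgArid1a replicates 1 and 2, against 4.55 and 4.48 in sgScramble, so the bound set beforehand could be applied to replicate 2 alone, and the median −log10 p was lower in both sgArid1a lists. Pairs of equal-length lists were compared by their strong regions, the upper 50% by fold. Replicate 2 lacked at least 3.38 times as many strong regions of a sgScramble list as it added. With strength by −log10 p the ratios were lower, at 2.75 and 3.31. The sgArid1a replicates also differed from each other (1075 against 515 by fold), and 1 library does not decide the question. Lower enrichment for a reason of handling, which 2 libraries per group with no batch labels cannot separate from the guide, and loss of ARID1A, which may act on distal sites and was not tested beyond the groups, stay open too.

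The rarity of losses at gene ends was weighed against the strength and width of those regions. A uniform drop in enrichment would spare strong, wide regions. Within strata of fold percentile and of width in the sgScramble lists the odds ratio was 0.429, with an upper 95% bound of 0.480. Here, and with strata of −log10 p, lost regions were compared with all other regions in both sgScramble lists. The main odds ratio compared them with regions in all lists. With strata of −log10 p, added later, the ratio was 0.541 with 10 strata and 0.524 with 50. The upper bounds were 0.607 and 0.588, past the bound of 0.5 set beforehand but still below 1. Strength and width may thus account for part of the rarity. Whether they account for the whole cannot be told, since the answer changed with the measure of strength. Regions present in all lists narrowed more distally than at gene ends: the ratio of the remaining lengths was 0.896 and 0.948 in the sgArid1a libraries and 0.995 and 1.01 in sgScramble, against narrowing by the same share everywhere, although the bound of 0.95 was set afterwards. A uniform drop in enrichment, lower depth or enrichment that bears unequally on distal sites, and an effect of ARID1A on them stay open.

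Several genes, such as Gsk3b and Yap1, had many lost regions, and the hypotheses of deletions and of gathering at a limited set of genes were tested by 100 shuffles within strata of −log10 p and distance. The longest run of neighbouring lost regions was 5, against a median of 6 (5 to 9) in the shuffles. This argues against long deletions of every copy but not against short ones. A run counts only regions with no peak in either sgArid1a list, so it cannot show the loss of some copies. Genes with 4 or more lost regions numbered 67, against a median of 70 (48 to 88), so such genes were no more frequent than their number of weak distal regions would give. With strata of fold in place of −log10 p the median was 102 (84 to 120), so a shortage of such genes may appear or not with the measure of strength. An effect of the guide on these genes in particular was not tested otherwise.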
